A study of Mus musculus with 12 samples.

How the data were processed

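The series holds 12 arrays of mouse spindle-cell malignant peripheral nerve sheath tumour cells, with 3 arrays each of control shRNA, Brd4 shRNA, vehicle and JQ1. Groups, replicate numbers, doses and days come from the sample labels. Total RNA was extracted with Trizol and labelled cRNA was made by the standard Affymetrix protocol, per the labels' protocols. The submitters' processing notes name MAS5, and its version and settings are not given in the sources used here. The deposited values are linear probe set intensity values (signals), not log-transformed, as their range shows. On every array their mean over probe sets, leaving out the highest and lowest 2%, was 500. This scaling by the authors was kept in the main setting, since it forces equal trimmed means and cannot show a change in the total amount of mRNA. Detection calls were not used here. No genome build is stated by these sources, so no coordinates are printed.

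Of 45101 probe sets, 64 are Affymetrix controls. The annotation table used here gives 1 gene symbol for 34945 of the others and several for 932, and 9160 are unnamed here. Symbols were checked through gene IDs against the RefSeq table used here, which matched 34741 probe sets and changed 0 symbols. No probe set is named Brd4, so its level was not analysed here. Probe sets with several symbols were not named. Each gene was read from the probe set with the highest mean over all 12 arrays, and from a probe set ending in _x_at only where it had no other. Signals were transformed as log2(signal + 16), and genes whose mean lay at or above the 40th percentile of all probe sets (a signal of 24.9) were tested, which left 12046 of 18193 genes.

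Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with trend, two-sided) in 1 fit of 4 groups, with 8 residual and 8.1 prior degrees of freedom. The contrasts were Brd4 shRNA minus control shRNA, JQ1 minus vehicle, and the difference between these effects. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Overlap between the first 2 contrasts was compared with that of independent lists by Fisher's exact test. The 26 gene lists held 497 genes, of which 454 had a named probe set and 398 were tested. They were tested with camera at a preset correlation of 0.01 between genes, with adjustment over all 78 list tests, and again with an estimated correlation. Of 23 calls, 1 held with the estimated correlation. The planned test fry, which does not compare a list with other genes, passed for some lists that camera did not call. Examples are RAS/MAPK output with Brd4 shRNA (fry adjusted p = 5.73e-07) and mitosis with JQ1 (fry adjusted p = 4.84e-06). It did not pass for interferon response with Brd4 shRNA (fry adjusted p = 0.736). Lists said below to pass or not to pass are judged by camera. Lists can share genes. In results without a call, the median and the mean or the test of a list can differ in sign: with Brd4 shRNA this held for the interferon, ATF4 and PRC2 lists, and with JQ1 for the pro-apoptotic, CDK inhibitor, RAS/MAPK and leukocyte lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

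Designs, lists, alternatives and the rule for the genes named in the text were fixed before the data were examined. The rule took the 8 genes with the largest rise and the 8 with the largest fall per comparison, among genes past the threshold whose 3 arrays of 1 group lay beyond all 3 of the other and whose brighter group was at or above the median of all probe sets. From each list it took up to 4 genes with the smallest adjusted p. Bcl2l11, Bcl2, Ccnd1, Myc, Hexim1 and Cdkn1a were named in both comparisons whatever their values. It also took the 5 genes raised and the 5 lowered in both comparisons with the largest smaller change, and the 5 most positive and 5 most negative differences. The text gives a part of the genes that the rule takes from the lists. Brd4 was in the rule and could not be given.

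The model was tested on simulated data made from the spread of these arrays. For the Brd4 shRNA comparison over 12046 genes, with 200 genes changed, it recovered 36% of those changed 1.25-fold, 58% at 1.5-fold, 82% at 2-fold and 98% at 4-fold, and 2.84% of its calls were false. In the data 41.1% of genes were called in this comparison, far more than were changed in the simulation, so these rates need not hold there. The ratio of 3' to 5' signal for actin was 1.18 to 1.23 with JQ1 and 1.25 to 1.29 with vehicle, so all 3 JQ1 arrays lay below all 3 vehicle arrays (exact permutation p = 0.1, the smallest possible for 3 arrays against 3). It did not separate Brd4 shRNA from control shRNA (exact permutation p = 0.4). The ratio for Gapdh was 0.827 to 0.869 over all arrays (exact permutation p = 0.9 with Brd4 shRNA and 0.2 with JQ1). Alternatives changed the offset, the filter, the scaling between arrays, the probe set rule, the eBayes options, the arrays in the fit, a replicate block, the size of change and each replicate in turn. No scan date or batch was used here.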

Results

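Messenger RNA was measured on 12 one-colour Affymetrix arrays in a mouse cell line model of spindle-cell malignant peripheral nerve sheath tumour, an aggressive sarcoma of the nerve sheath. The cells derive from skin-derived precursors that lack Nf1, a brake on RAS signalling, and the tumour suppressor p53. There were 4 groups of 3 arrays. Cells with a doxycycline-inducible control shRNA and cells with a doxycycline-inducible shRNA against Brd4 were taken on day 3 after 1 ug/mL doxycycline. Cells given vehicle and cells given 500 nM JQ1, an inhibitor of the acetyl-lysine binding pockets (bromodomains) of the BET proteins Brd2, Brd3, Brd4 and Brdt, were taken on day 2. The arrays had been scaled to 1 trimmed mean of 500, and the median signal of an array lay between 42.7 and 54.6. Arrays of the same group correlated at r = 0.9898 to 0.9913 across genes, and no pair of arrays held identical values. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision. Of 18193 genes with a probe set, 12046 passed the signal filter and were tested. Values below are log2 fold changes ± standard error with n = 3 arrays per group, on the log2(signal + 16) scale, which understates the change of dim genes. Adjusted p-values are from limma with Benjamini-Hochberg adjustment, a change is named as such where the adjusted p is under 0.05, and signals are means ± SD. Counts within a list are over all genes tested, and the count adjusted over the list alone was the same unless it is given beside it.

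The first comparison asked how the transcriptome of the tumour cells responds to knockdown of Brd4, a reader of acetylated chromatin that recruits the elongation kinase P-TEFb. The level of Brd4 itself was not analysed here, because the annotation table used here names no Brd4 probe set, so the knockdown was not checked on these arrays. The sample titles name the same Brd4 hairpin for every array of that group. Effects particular to this hairpin cannot be told apart from those of lowering Brd4. With the Brd4 shRNA, the most raised genes were replication-dependent and variant histone genes, the thioredoxin-binding protein gene Txnip and the immediate early transcription factor genes Fos and Egr1. Txnip rose by 3.07 ± 0.10 (adjusted p = 7.33e-13), from a signal of 192.9 ± 37.5 to 1720 ± 107. Fos rose by 2.86 ± 0.10 and Egr1 by 2.21 ± 0.10. The histone genes H3c11, H2ac19, H2aw, H2bc21 and H2bc22 rose by between 2.31 and 3.07. The 8 most lowered genes were Vkorc1, which recycles vitamin K, Rcan2, the thymidine kinase gene Tk1, the vasodilator peptide gene Adm, the serotonin receptor gene Htr1b, Inmt, Emb and the proteoglycan gene Ogn. Vkorc1 fell to -2.65 ± 0.08 (adjusted p = 5.66e-13), from a signal of 2850 ± 66.3 to 444.8 ± 63.9. Tk1 fell to -2.27 ± 0.07 and Adm to -2.21 ± 0.06. All 3 arrays of 1 group lay beyond all 3 of the other for each of these 16 genes, which was a condition for naming them.

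Among the genes fixed in advance, Bcl2l11, which encodes the pro-apoptotic protein Bim, rose by 0.49 ± 0.13 with the Brd4 shRNA (adjusted p = 0.00598). Bcl2, which opposes Bim, fell to -0.91 ± 0.16 (adjusted p = 0.000182). The cyclin D1 gene Ccnd1 fell to -0.39 ± 0.05 (adjusted p = 5.79e-06). Hexim1, which encodes an inhibitor of P-TEFb, fell to -1.13 ± 0.07 (adjusted p = 4.5e-09). The p21 gene Cdkn1a rose by 0.51 ± 0.17 (adjusted p = 0.0273), a call that was lost without control shRNA replicate 2 or 3 and without Brd4 shRNA replicate 2 or 3, at adjusted p = 0.118, 0.0717, 0.124 and 0.0705. It was also lost with scaling to the poly-A spike-in probe sets (0.46, adjusted p = 0.084). Myc stood at 0.15 ± 0.06 (adjusted p = 0.0585). It passed the threshold when only the 6 arrays of this comparison were fitted (adjusted p = 0.0461).

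**Figure D1:**
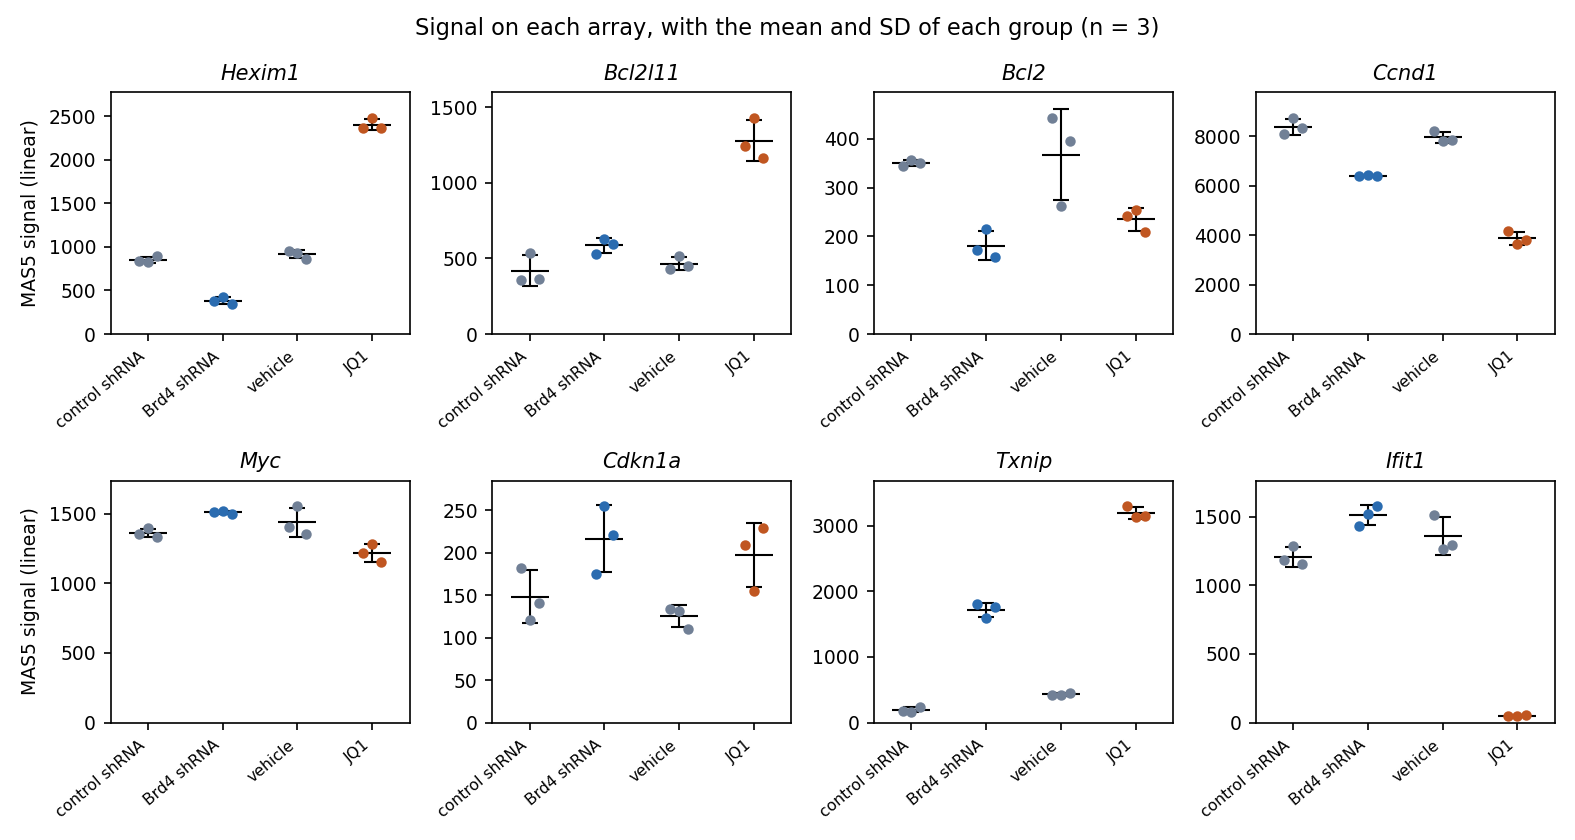
MAS5 signal (linear scale, vertical axis from 0) of 8 genes on each of the 12 arrays, by group. Points are arrays, the horizontal line is the group mean and the bar its SD (n = 3). Hexim1 lies at 382.8 with Brd4 shRNA and at 2402 with JQ1, against 851.7 and 914.7 in the control shRNA and vehicle groups.

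Of the 26 gene lists fixed in advance, 9 shifted with the Brd4 shRNA in camera's competitive test, 6 down and 3 up. None of the 9 passed with an estimated correlation between genes, whose adjusted p is given for each. Mitosis genes fell: 17 of 27 were lower and 1 higher, with a median of -0.24 (adjusted p = 5.03e-05, and adjusted p = 0.0846 with an estimated correlation). They included the mitotic kinesin gene Kif20a at -0.78 ± 0.06, the contractile ring gene Anln at -0.62 ± 0.05, Cdc20 at -0.61 ± 0.06 and the kinase gene Plk1 at -0.60 ± 0.05. MYC and ribosome biogenesis genes were lower in 16 of 30 and higher in 3 (4 adjusted over the list alone), among them the spermidine synthase gene Srm at -0.53 ± 0.06 and Nolc1 at -0.40 ± 0.05 (adjusted p = 0.00547, and adjusted p = 0.241 with an estimated correlation). Extracellular matrix genes were lower in 17 of 29 and higher in 7 (18 and 8 adjusted over the list alone), with a median of -0.41 (adjusted p = 0.00703, and adjusted p = 0.423 with an estimated correlation). The collagen gene Col3a1 stood at -1.42 ± 0.09 and the stromelysin gene Mmp3 at -1.49 ± 0.09, while Timp1, an inhibitor of such proteases, rose by 0.72 ± 0.04. Cholesterol synthesis genes were lower in 11 of 20 and higher in 1, including Mvd at -0.65 ± 0.07 and Hmgcs1 at -0.63 ± 0.08 (adjusted p = 0.00756, and adjusted p = 0.241 with an estimated correlation). That call was lost with scaling to the poly-A spike-in probe sets (adjusted p = 0.0553). Hypoxia and glycolysis genes were lower in 8 of 22 and higher in 1, led by Adm, Ddit4 at -0.91 ± 0.07 and the oxygen sensor gene Egln3 at -0.76 ± 0.07 (adjusted p = 0.0167, and adjusted p = 0.529 with an estimated correlation). Smooth muscle and myofibroblast genes were lower in 5 of 10 and higher in 1 (6 lower adjusted over the list alone), including Myl9 at -0.96 ± 0.15 and Cnn2 at -0.53 ± 0.05 (adjusted p = 0.0364, and adjusted p = 0.282 with an estimated correlation). This last call was lost without control shRNA replicate 2 (adjusted p = 0.0714), without Brd4 shRNA replicate 1 (adjusted p = 0.0568) and with no filter on dim probe sets (adjusted p = 0.0834).

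The lists that shifted upwards with the Brd4 shRNA were histone genes, lysosome and autophagy genes, and cytokines and NF-kappaB targets. Histone genes were higher in 6 of 11 and lower in 1, with a median of 0.65 (adjusted p = 0.000133, and adjusted p = 0.0846 with an estimated correlation). The linker histone gene H1f2 rose by 2.10 ± 0.04, to a signal of 19010, and the DNA damage variant gene H2ax by 1.42 ± 0.07. Lysosome and autophagy genes were higher in 15 of 25 and lower in none (16 and 1 adjusted over the list alone), among them Hexa at 0.68 ± 0.06 and the proton pump gene Atp6v0d1 at 0.57 ± 0.05 (adjusted p = 5.03e-05, and adjusted p = 0.222 with an estimated correlation). Cytokines and NF-kappaB targets were higher in 9 of 16 and lower in 2 (10 higher adjusted over the list alone). The neutrophil chemokine gene Cxcl1 rose by 1.42 ± 0.10, Nfkbiz by 1.15 ± 0.09 and Nfkbia by 0.62 ± 0.04, while Cxcl12 fell to -0.56 ± 0.05 (adjusted p = 0.00825, and adjusted p = 0.15 with an estimated correlation).

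The other 17 lists did not pass. BET proteins and P-TEFb were higher in 5 of 16 and lower in 3, with Brd2 at 0.69 ± 0.05 and the P-TEFb kinase gene Cdk9 at 0.56 ± 0.06. G1/S cyclins and CDKs were lower in 7 of 15 and higher in 4, with Ccnd2 at -0.51 ± 0.05 and Ccne2 at -0.77 ± 0.08. Interferon response genes were higher in 5 of 20 and lower in 3, with Rsad2 at 0.91 ± 0.11 (0.57 with its probe sets averaged) and Psmb8 at -0.60 ± 0.07. RAS/MAPK output genes were higher in 8 of 19 and lower in 4 (5 lower adjusted over the list alone), with Ier3 at 0.93 ± 0.05 and Dusp6 at 0.65 ± 0.04. This list passed with scaling to the poly-A spike-in probe sets (adjusted p = 0.000116). ATF4 and unfolded protein response genes were lower in 8 of 25 and higher in 4, with Ddit3 at 1.07 ± 0.05 and Creld2 at -0.60 ± 0.05. DNA replication genes were lower in 12 of 32 and higher in 7. Pro-apoptotic BCL2 family genes were higher in 3 of 8 and lower in 1, and anti-apoptotic regulators were lower in 4 of 8 (5 adjusted over the list alone) and higher in 1. CDK inhibitors were higher in 2 of 6 and lower in 1, neural crest and skin precursor genes higher in 8 of 15 and lower in 2, Schwann cell lineage genes lower in 3 of 9 (2 adjusted over the list alone), and PRC2 genes higher in 1 (0 adjusted over the list alone) and lower in 1 of 11. Macrophage and leukocyte markers were lower in 1 of 6, namely Cd14 at -1.02 ± 0.11, endothelial markers lower in 1 of 5, neuron markers higher in 2 and lower in 2 of 9, and no epithelial (3 tested) or adipocyte (3 tested) marker passed.

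In all, 4949 of 12046 genes differed between Brd4 shRNA and control shRNA, 2584 higher and 2365 lower, of which 115 and 223 differed by at least 2-fold. Scaling moved the balance: subtracting each array's median gave 2802 higher and 1548 lower, and scaling to the poly-A spike-in probe sets gave 953 higher and 1576 lower. The rise of H3c11, whose control signal was 13.1, was 1.89 with an offset of 64, and averaging all of a gene's probe sets put Rcan2 (-1.44 with an offset of 64) at -1.33, Htr1b at -1.41 and Emb at -0.82.

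The second comparison asked how the same tumour cells respond to the BET inhibitor. With JQ1 the most lowered genes were the calcification inhibitor gene Mgp, interferon-induced genes (Rtp4, Ifit1), chemokine and matrix genes (Ccl5, Mmp3), the decoy receptor gene Tnfrsf11b, the potassium channel gene Kcnn4 and Cd300lb. Mgp fell to -4.82 ± 0.07 (adjusted p = 1.45e-17), from a signal of 6786 ± 122 to 226 ± 21.3. Ifit1 fell to -4.37 ± 0.08, from 1358 ± 137 to 50.1 ± 2.67, and Ccl5 to -3.90 ± 0.11. The signals of Tnfrsf11b and Kcnn4 with JQ1, 6.52 and 12.4, lay under the filter level of 24.9. The most raised genes were Txnip at 2.85 ± 0.10 (adjusted p = 4.22e-13), Id1, an inhibitor of differentiation factors, at 2.70 ± 0.11, the stress-induced genes Atf3 at 2.34 ± 0.12 and Chac1 at 2.22 ± 0.06, the transcription factor gene Klf2 at 2.16 ± 0.14, Serpini1, H2bc21 and Rnf157.

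Bcl2l11 rose by 1.43 ± 0.13 with JQ1 (adjusted p = 1.01e-07), from a signal of 465.6 to 1279. Bcl2 stood at -0.58 ± 0.16 (adjusted p = 0.00496), a call lost when the probe sets of the gene were averaged (-0.35, adjusted p = 0.0707). Ccnd1 fell to -1.04 ± 0.05 (adjusted p = 2.24e-11). Hexim1 rose by 1.38 ± 0.07 (adjusted p = 1.28e-10). Cdkn1a rose by 0.59 ± 0.17 (adjusted p = 0.00937), which was lost without JQ1 replicate 3 (adjusted p = 0.0507). Myc fell to -0.24 ± 0.06 (adjusted p = 0.00316), which was lost after subtracting each array's median (-0.16, adjusted p = 0.142) and with scaling to the poly-A spike-in probe sets (-0.16, adjusted p = 0.389).

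With JQ1, 9 lists shifted, 5 down and 4 up, and none of the 9 passed with an estimated correlation. Interferon response genes fell the most: 17 of 20 were lower and none higher, with a median of -1.78 (adjusted p = 6e-09, and adjusted p = 0.0939 with an estimated correlation). Besides Ifit1 they included the antiviral genes Rsad2 at -2.98 ± 0.11, Ifit2 at -2.11 ± 0.06 and Ifitm3 at -1.91 ± 0.05. Cytokines and NF-kappaB targets were lower in 11 of 16 and higher in 2, with Cxcl10 at -3.77 ± 0.09, Ccl2 at -2.06 ± 0.06 and Cxcl12 at -1.76 ± 0.05 (adjusted p = 0.000255, and adjusted p = 0.0846 with an estimated correlation). Beside these lists, the leukocyte marker Cd14 fell to -2.25 ± 0.11, the 1 of 6 tested markers of macrophages and leukocytes that passed. Extracellular matrix genes were lower in 21 of 29 and higher in 2, with the proteoglycan gene Dcn at -3.50 ± 0.07, the collagen gene Col6a3 at -2.60 ± 0.06 and Tnc at -1.99 ± 0.05 (adjusted p = 2.57e-07, and adjusted p = 0.158 with an estimated correlation). Cholesterol synthesis genes were lower in 13 of 20 and higher in none, with Nsdhl at -1.12 ± 0.05 and Cyp51 at -0.63 ± 0.04 (adjusted p = 0.000133, and adjusted p = 0.15 with an estimated correlation). Anti-apoptotic regulators were lower in 6 of 8 and higher in none, with the caspase-binding protein gene Birc3 at -1.97 ± 0.12 and Bcl2l2 at -0.53 ± 0.08 (adjusted p = 0.0396, and adjusted p = 0.241 with an estimated correlation). This call was lost with the 60th-percentile filter (adjusted p = 0.0623), in the fit of 6 arrays (adjusted p = 0.0683), and without vehicle replicate 1 or 3 or JQ1 replicate 1 (adjusted p = 0.0539, 0.0562 and 0.0521).

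ATF4 and unfolded protein response genes rose with JQ1: 17 of 25 were higher (18 adjusted over the list alone) and 5 lower (adjusted p = 5.66e-05, and adjusted p = 0.15 with an estimated correlation). The higher members included Chac1, Atf3, the stress transcription factor gene Ddit3 at 1.46 ± 0.05 and the amino acid transporter gene Slc7a5 at 0.98 ± 0.04. The cystine transporter gene Slc7a11 was among the lower members. Lysosome and autophagy genes were higher in 16 of 25 and lower in 5, with the sialidase gene Neu1 at 1.61 ± 0.12 and the autophagosome gene Map1lc3b at 0.72 ± 0.04 (adjusted p = 0.000234, and adjusted p = 0.241 with an estimated correlation). Histone genes were higher in 8 of 11 and lower in 2, with H2bc21 at 2.13 ± 0.08, H1f2 at 1.08 ± 0.04 and H2az2 at 0.74 ± 0.05 (adjusted p = 0.00825, and adjusted p = 0.15 with an estimated correlation). BET proteins and P-TEFb were higher in 10 of 16 (11 adjusted over the list alone) and lower in 2, led by Brd2 at 1.40 ± 0.05 and Hexim1 (adjusted p = 0.0364, and adjusted p = 0.15 with an estimated correlation). The call of this list was lost with the 60th-percentile filter (adjusted p = 0.0624).

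The other 17 lists did not pass with JQ1. G1/S cyclins and CDKs were lower in 7 of 15 and higher in 2 (3 adjusted over the list alone), with Cdk6 at -1.15 ± 0.09, Skp2 at -0.60 ± 0.05 and the retinoblastoma gene Rb1 at 0.76 ± 0.07. Mitosis genes were lower in 10 of 27 and higher in 4 (11 and 5 adjusted over the list alone), with Ccnb2 at -1.05 ± 0.05. RAS/MAPK output genes were higher in 10 of 19 and lower in 7, with Fosl1 at -1.38 ± 0.06 and Spred2 at -0.76 ± 0.05 against Dusp4 at 0.85 ± 0.06. Neural crest and skin precursor genes were lower in 5 of 15 (6 adjusted over the list alone) and higher in 4, with Sox2 at -1.49 ± 0.08. Neuron markers were lower in 5 of 9 and higher in 1, with the neurofilament gene Nefm at -1.09 ± 0.06. This list passed after subtracting each array's median (adjusted p = 0.0401) and with scaling to the poly-A spike-in probe sets (adjusted p = 0.0043). DNA replication genes were lower in 12 of 32 (13 adjusted over the list alone) and higher in 7, and MYC and ribosome biogenesis genes lower in 16 of 30 and higher in 7. Hypoxia and glycolysis genes were lower in 11 of 22 and higher in 3, with Adm at -2.48 ± 0.06, and smooth muscle and myofibroblast genes lower in 6 of 10 and higher in 2. The hypoxia list passed with no filter on dim probe sets (adjusted p = 0.0448), after quantile normalization (adjusted p = 0.0256) and without vehicle replicate 1 (adjusted p = 0.0293). Pro-apoptotic BCL2 family genes were higher in 2 of 8, Bcl2l11 and Bid (0.77 ± 0.06), and lower in 2, Bok (-0.96 ± 0.09) and Bak1 (-0.60 ± 0.08). CDK inhibitors were higher in 3 of 6 and lower in 2, the latter including Cdkn2a at -1.89 ± 0.18. Schwann cell lineage genes were lower in 3 of 9, and PRC2 genes higher in 4 and lower in 1 of 11. Endothelial and adipocyte markers were each lower in 1 gene, of 5 and 3 tested, and none of 3 epithelial markers passed.

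With JQ1, 6120 of 12046 genes differed from vehicle, 2804 higher and 3316 lower, and at least 2-fold changes numbered 164 higher and 686 lower. After subtracting each array's median, 3100 were higher and 2452 lower. Of 3120 further probe sets called with JQ1 for genes that were called too, 316 went in the opposite direction to the gene. With Brd4 shRNA these were 155 of 2203. Averaging all of a gene's probe sets put Rtp4 at -2.91, Serpini1 at 1.00, Rnf157 at 0.86, Birc3 at -1.28, Bcl2l2 at -0.33 and Neu1 at 0.96. Tnfrsf11b stood at -7.08 without an offset and at -2.62 with an offset of 64.

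**Figure D2:**
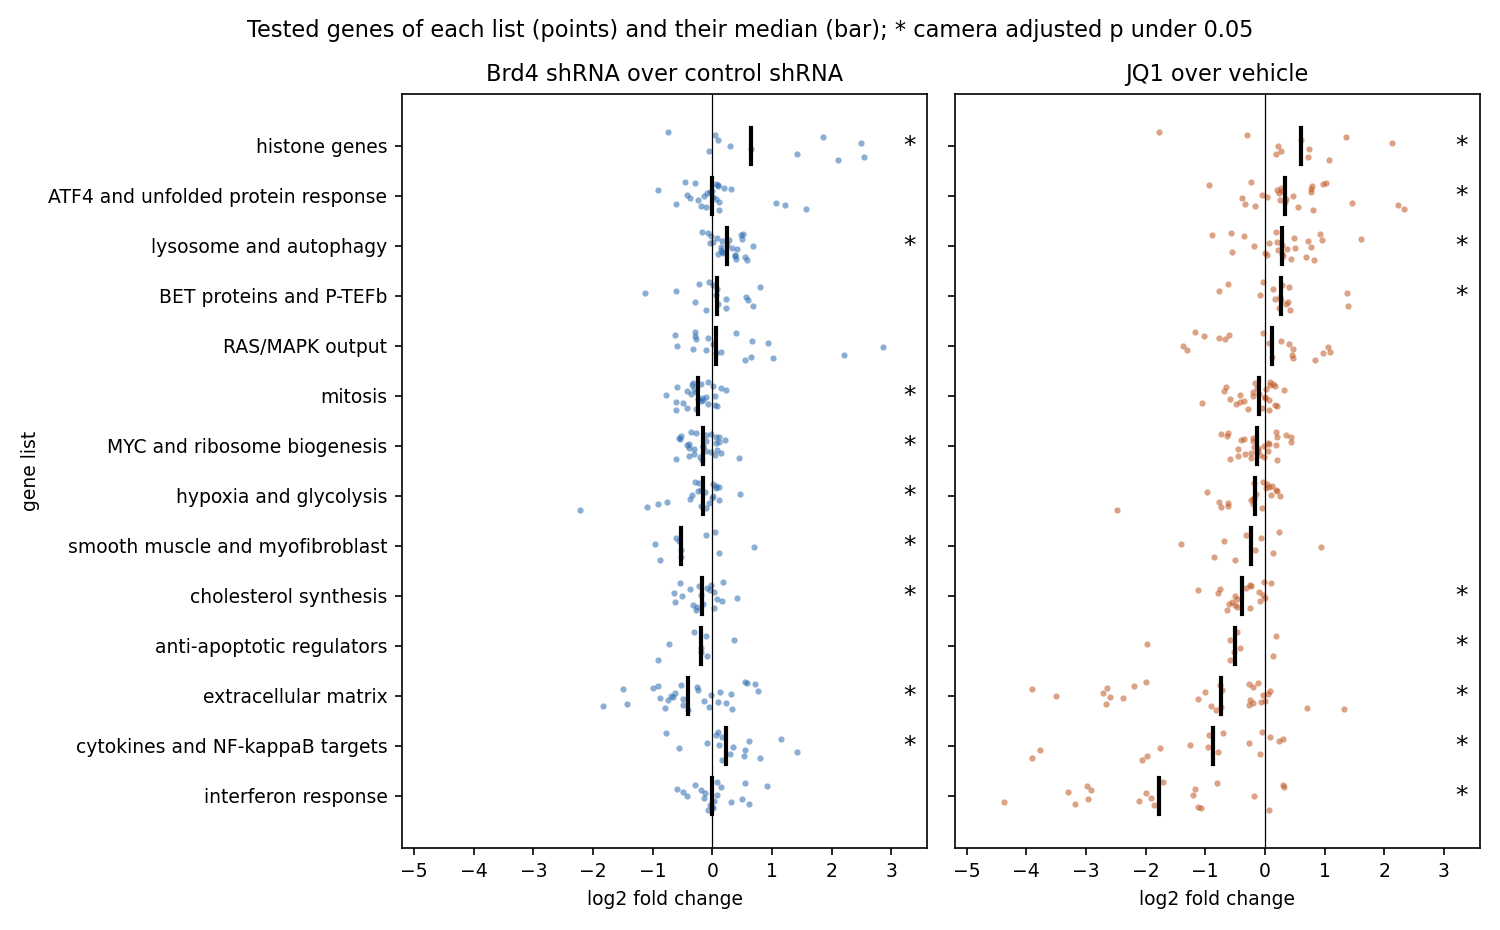
Log2 fold change (horizontal axis) of the tested genes of the 14 lists that shifted in at least 1 of the 3 contrasts, with Brd4 shRNA on the left and JQ1 on the right. Points are genes, the vertical bar is the list's median and an asterisk marks a camera adjusted p under 0.05. The interferon median lies at -1.78 with JQ1.

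The drug and the knockdown were set side by side to see which responses they share. Days, controls and means of delivery also differ between them, so their difference mixes these with the perturbation. Both raised Txnip, H2bc21, Rnf157, Atf3 and Gm5617, and both lowered Rcan2, Adm, Htr1b, Inmt and Ogn, the genes with the largest smaller change in each direction. Adm stood at -2.21 ± 0.06 with Brd4 shRNA and at -2.48 ± 0.06 with JQ1, and Inmt at -2.13 ± 0.07 and -2.17 ± 0.07. Rcan2 stood at -2.27 ± 0.20 and -3.41 ± 0.20, with a JQ1 signal of 5.73 that lies under the filter level, and the JQ1 value was -5.26 without an offset. With its probe sets averaged, Rcan2 stood at -2.02 and Htr1b at -1.47 with JQ1, and Rnf157 at 0.92 with Brd4 shRNA. The extracellular matrix and cholesterol synthesis lists shifted down in both comparisons, and the histone and lysosome lists shifted up in both. None of these 8 calls held with an estimated correlation (adjusted p = 0.0846 to 0.423), and the cholesterol call with Brd4 shRNA was lost with scaling to the poly-A spike-in probe sets. Of 3305 genes called in both comparisons, 2573 changed in the same direction. The 1256 genes higher in both compare with 601.5 for independent lists (Fisher's exact test, two-sided, p = 2.72e-232), and the 1317 lower in both with 651 (p = 2.95e-234). The comparisons share no control arrays, but 1 fit gave each gene the same standard error in both. A gene with a small error is more easily called in both, so the numbers for independent lists may be too low. Fitting each comparison on its own 6 arrays gave 2481 genes changed in the same direction. Genes are not independent replicates, which makes these p-values too small. At least 2-fold changes in the same direction in both numbered 31 higher and 110 lower. Across genes, the log2 fold changes of both comparisons correlated at r = 0.41 (Spearman's rho 0.35). After subtracting each array's median, 1395 genes were higher in both and 797 lower, and scaling to the poly-A spike-in probe sets gave 508 and 709.

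**Figure D3:**
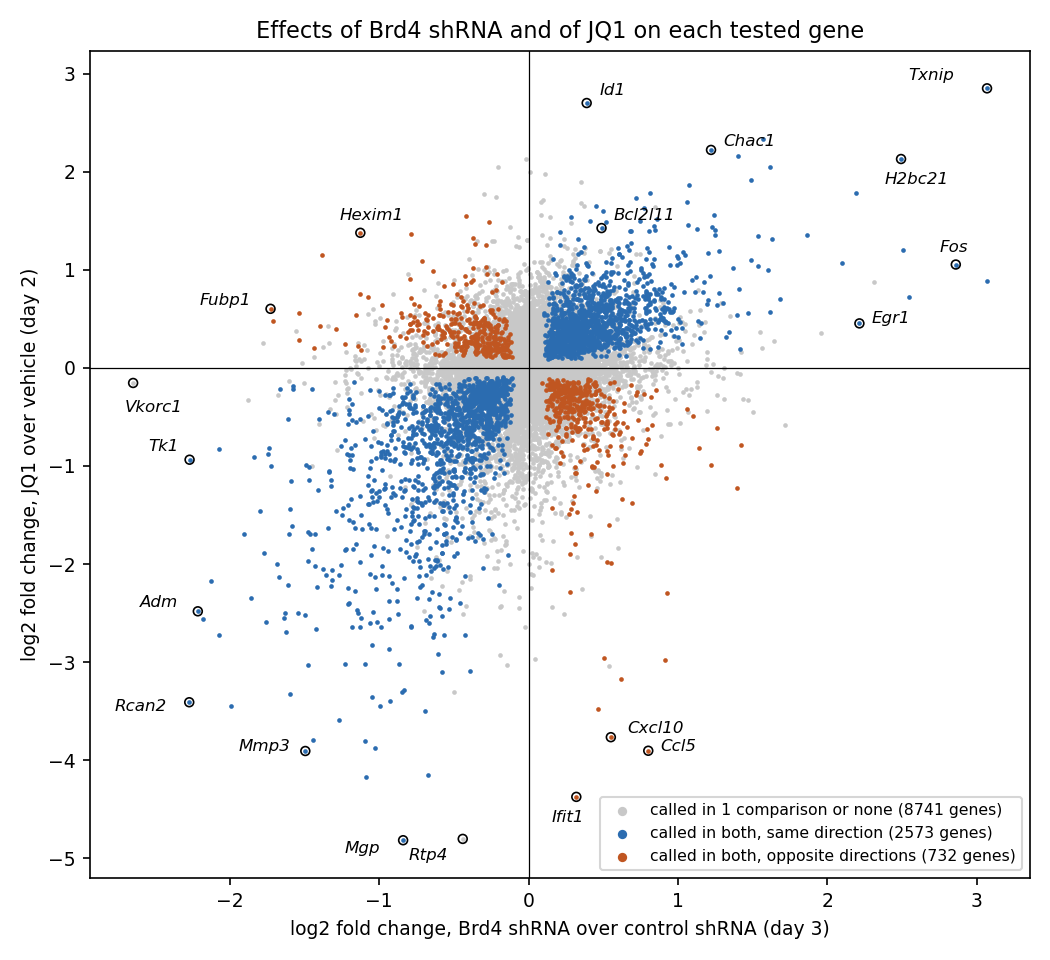
Log2 fold change with JQ1 (vertical axis) against that with Brd4 shRNA (horizontal axis) for the 12046 tested genes, 1 point per gene. Blue points are the 2573 genes called in both comparisons in the same direction, orange points the 732 called in opposite directions and grey points the rest. Hexim1 lies at -1.13 and 1.38, and Ccl5 at 0.80 and -3.90.

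The effects of JQ1 and of Brd4 shRNA differed past adjusted p 0.05 for 4501 genes, and the JQ1 effect was the higher for 1887 and the lower for 2614. Scaling to the poly-A spike-in probe sets gave 1314 and 943. The most negative differences were those of Ccl5 (-4.71 ± 0.16, adjusted p = 3.08e-12), Ifit1 (-4.69 ± 0.11), Rtp4, Cxcl10 and Mgp. Ccl5 rose by 0.80 ± 0.11 and Cxcl10 by 0.55 ± 0.09 with Brd4 shRNA, and both fell with JQ1. Mgp fell in both, to -0.84 ± 0.07 and -4.82 ± 0.07. The most positive differences were those of Sp6 (2.54 ± 0.63, adjusted p = 0.00422), Hexim1 (2.50 ± 0.10, adjusted p = 2.1e-11), Vkorc1 (2.49 ± 0.11), Fubp1 (2.33 ± 0.10) and Id1 (2.31 ± 0.15). Vkorc1 stood at -0.15 ± 0.08 with JQ1 (adjusted p = 0.122). The call of Sp6 was lost when its probe sets were averaged (0.73, adjusted p = 0.054), and that setting put Fubp1 at 0.96 and the difference of Rtp4 at -2.67. Sp6 stood at 3.92 without an offset and at 1.33 with an offset of 64. Among the lists, the JQ1 effect was the lower for interferon response genes in 16 of 20 and the higher in none (1 adjusted over the list alone), with a median difference of -1.78 (adjusted p = 5.65e-09, and adjusted p = 0.0939 with an estimated correlation). Cytokines and NF-kappaB targets were lower in 12 of 16 (13 adjusted over the list alone), with a median difference of -1.10 (adjusted p = 8.9e-09), and this was the 1 list call of 23 that held with an estimated correlation (adjusted p = 0.0243). Extracellular matrix genes were lower in 20 of 29 and higher in 5 (adjusted p = 5.03e-05, and adjusted p = 0.241 with an estimated correlation). RAS/MAPK output genes were lower in 12 of 19 and higher in 4 (adjusted p = 0.00825, and adjusted p = 0.0939 with an estimated correlation). ATF4 and unfolded protein response genes had the higher JQ1 effect in 18 of 25 (19 adjusted over the list alone) and the lower in 1 (adjusted p = 1.63e-08, and adjusted p = 0.0853 with an estimated correlation). The difference of 3 other lists passed in some settings, of which 1 is given for each: histone genes (adjusted p = 0.0185 with scaling to the poly-A spike-in probe sets), cholesterol synthesis (adjusted p = 0.0381 after quantile normalization) and neuron markers (adjusted p = 0.0043 with scaling to the poly-A spike-in probe sets).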

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

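The leukocyte test, the test of S phase and 1 bound of the test of starting levels were chosen after the result was seen. The effects of JQ1 and Brd4 shRNA differed for 4501 genes, and 732 genes were called in opposite directions with the difference itself past the threshold. Independent lists would give 711.3 genes higher with Brd4 shRNA and lower with JQ1, against 385 found. They would give 550.5 with the reverse directions, against 347 found, so these 732 genes are fewer than for independent lists. Those among the 5 most positive and 5 most negative differences of the log2 effects were Hexim1 (2.50), Fubp1 (2.33) and Sp6 (2.54), which fell with Brd4 shRNA and rose with JQ1, and Ccl5 (-4.71), Ifit1 (-4.69) and Cxcl10 (-4.32), which did the opposite. Lists whose effects differed were extracellular matrix (median -0.63), interferon response (-1.78), cytokines and NF-kappaB targets (-1.10), RAS/MAPK output (-0.54) and ATF4 and unfolded protein response (0.39). With an estimated correlation only the cytokine list held (adjusted p = 0.0243), against adjusted p = 0.241 for extracellular matrix, 0.0939 for interferon response, 0.0939 for RAS/MAPK output and 0.0853 for ATF4. In the joint splits of both sets of 6 arrays, 1 of 100, the real one, gave as many genes with a difference (4501, the highest other 3163). That highest other split kept the JQ1 arrays apart from the vehicle arrays, with their labels exchanged. Splits that kept neither real grouping gave 0, and since all of them mix treated and control arrays they say little about chance.

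For the 732 genes called in opposite directions, control cultures that start at different levels are argued against as the main cause, although vehicle and control shRNA differed in 1407 of all tested genes (11.7%), 43 of them at least 2-fold. In 4.51% of the 732 genes the treated groups ended closer to each other than their controls were, and for Hexim1 vehicle and control shRNA differed by 0.10 while JQ1 and Brd4 shRNA differed by 2.60. The choice of probe set stays open for part of them: of the 436 with another bright probe set, 68.3% had opposite signs there too (95% Wilson interval 63.8 to 72.5), against 36.9% of other genes, and 63.5% had both signs as in the brightest probe set. Scaling stays open for part of them, since 85.1% kept opposite calls after quantile normalization, 58.7% after subtracting each array's median and 30.1% with scaling to the poly-A spike-in probe sets. All 732 kept opposite signs under these settings. This says little, since the settings shifted log2 fold changes by medians of only -0.051 to 0.077, and genes already called would mostly keep their signs. Blocking the bromodomains of several BET proteins may differ in its biology from lowering Brd4. This difference, effects particular to the hairpin used and the difference in day may also contribute and were not tested.

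The fall of interferon genes with JQ1 and not with Brd4 shRNA was weighed next. The list was higher in vehicle than in control shRNA by a median of 0.38 (bootstrap 95% interval 0.161 to 0.699), against a fall to -1.78, and with JQ1 it lay at -0.83 against control shRNA (-1.945 to -0.264). The bound set first, an interval under 0.446, was not met, since the interval reaches 0.699. The bound added after that test was met, but it was set on the same values. JQ1 against control shRNA also mixes day and doxycycline with the drug. These values lean against a higher start as the whole cause without settling it. With JQ1 the list lay below control shRNA, at -0.83, but at -1.78 against vehicle, so the share of a higher start stays open. Leukocytes in the vehicle cultures cannot be told apart with the markers at hand, whose median was 0.06 with JQ1 over 6 tested genes (-1.24 to 0.389). Cd14, which other cells also make, had a signal of 557 in vehicle, while Ptprc (3.12), Tyrobp (11.3) and Lyz2 (36.1) were dim.

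The histone list was called higher in both comparisons, with 6 of 11 higher and 1 lower with Brd4 shRNA, and 8 and 2 with JQ1. Neither call held with an estimated correlation (camera adjusted p = 0.0846 with Brd4 shRNA and 0.15 with JQ1). Cross-hybridisation within the family was checked in a wider set of 20 tested histone genes, and is argued against as the whole cause. The 12 genes read by plain _at probe sets had medians of 0.81 with Brd4 shRNA and 0.66 with JQ1. Their bootstrap intervals were 0.387 to 1.64 and 0.268 to 1.00. A partial share stays open, since the 8 others, H2aw, H2bc21 and H2bc22 among them, had medians of 1.37 and 0.81. More cells in S phase is argued against as the main cause. The DNA replication list did not rise, with medians of -0.06 and -0.09 and upper bounds of 0.05 and 0.04. A partial share stays open, since its members went both ways, with 7 higher and 12 lower of 32 in each comparison. A rise of polyadenylated histone transcripts on both treatments is a hypothesis that stays, found and tested on the same data, and a change of polyadenylation itself may give the same signal.

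Signals outside the tested genes were as follows. Among probe sets unnamed here, 62 differed at least 2-fold with Brd4 shRNA and 114 with JQ1. The Affymetrix control probe set for the 3' end of the transferrin receptor mRNA stood at -0.74 with Brd4 shRNA and 0.61 with JQ1, and that for the 3' end of pyruvate carboxylase at -0.46 and 0.66. A control probe set named MUR_b2 stood at 0.35 and 0.51.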

How the results depend on the processing

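Direction and side of the threshold were followed for each result under the alternatives fixed before the data were examined. No test here was chosen after the result was seen. Other settings for the Brd4 fold change could not be run, since no probe set is named Brd4 here. Counts within 1.5 times the main count are not repeated. With scaling to the poly-A spike-in probe sets, Brd4 shRNA gave 2529 genes, the difference between effects 2257 and genes changed the same way in both comparisons 1217. The mean log2 signal of these probe sets had an SD of 0.0474 to 0.203 within groups. Scaling to them passes that spread on to all genes of an array. Whether this is the cause of the lower counts was not tested. Testing all probe sets gave 8448 with Brd4 shRNA, 10880 with JQ1, 7601 for the difference and 4116 the same way in both, as more features were tested. Requiring at least 2-fold as well gave 338, 850, 759 and 141. Genes called in opposite directions numbered 224 with poly-A scaling, 472 with averaged probe sets and 1166 with all probe sets, against 732. Leaving out 1 replicate gave 4345 to 4734 genes with Brd4 shRNA, 5589 to 5727 with JQ1, 4081 to 4437 for the difference, 2341 to 2487 the same way in both and 22 to 25 list shifts. Other settings gave 21 to 26 list shifts. Among named genes, 4 values turned sign when a gene's probe sets were averaged: with Brd4 shRNA Cflar (-0.13), Pola1 (0.033) and Eng (-0.33), and with JQ1 Nsd3 (0.013); the cause was not tested. Of 2674 values of named genes under the other alternatives, 2607 kept direction and side, 50 lost the call and 13 gained it. Of 898 list values, 881 kept both, 6 lost the call and 11 gained it. Sign changes of values with no call before or after count as kept; there were 27 among named genes and 58 among list medians, leaving out replicates included. Equal replicate numbers did not pair the samples (correlations of their deviations -0.0758 to 0.0319, and 1 of 6 samples correlated best with its own number). The replicate block gave 4799 genes with Brd4 shRNA, 5973 with JQ1 and 4285 for the difference, of which 4671, 5871 and 4168 were also called without it. Of the named genes and lists, it moved 5 calls, all with Brd4 shRNA: Cdkn1a (adjusted p = 0.058) and the smooth muscle list (0.0519) no longer passed, while Myc (0.0494), Ezh2 (0.0457) and Laptm5 (0.00735) passed. Splits of 6 arrays number 10, too few for a share under 0.05: for Brd4 shRNA 1 split gave as many genes (real 4949, highest other 0), and for JQ1 likewise (real 6120, highest other 0). For genes changed the same way, 1 of 100 joint splits gave as many (real 2573, highest other 0). As no other split of either comparison called any gene, this count is 0 in all others and does not test chance. For list shifts 1 of 100 gave as many (real 23, highest other 20), which does not exclude chance for single lists: 77 splits that kept neither real grouping gave 0 to 14 list shifts, with a median of 8. These splits still hold treated and control arrays in uneven numbers. Genes near the filter signal of 24.9 have fold changes that depend on the offset.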

Other observations

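Gene groups not fixed in advance were tested after the results were seen, as 9 lists in 3 contrasts with adjustment over these 27 tests. With Brd4 shRNA, genes of respiratory complex I, the entry point of the mitochondrial electron transport chain, were higher in 19 of 33 and lower in none, with a median of 0.17 (camera adjusted p = 6.53e-05, and adjusted p = 0.59 with an estimated correlation). Ndufa3 stood at 0.48 ± 0.04 and Ndufa7 at 0.51 ± 0.04. The median was 0.12 with scaling to the poly-A spike-in probe sets, where 4 genes were higher. Amino acid transporter genes were higher with JQ1 in 6 of 13 and lower in 1 (adjusted p = 0.0387, and adjusted p = 0.311 with an estimated correlation), with Slc1a4 at 1.07 ± 0.13 and Slc3a2 at 0.78 ± 0.05, while Slc7a11, which imports cystine, stood at -0.94 ± 0.13. The JQ1 effect on these genes was higher than that of Brd4 shRNA in 5 and lower in 2 (adjusted p = 0.0387, and adjusted p = 0.311 with an estimated correlation). Some of these genes also belong to the ATF4 list. Ribosomal protein genes were higher with Brd4 shRNA in 12 of 42 and lower in 2, with a median of 0.09 (adjusted p = 0.0387, and adjusted p = 0.967 with an estimated correlation). After quantile normalization the median was -0.005, with 4 higher and 2 lower (camera unadjusted p = 0.804). Scaling to the poly-A spike-in probe sets gave 0 higher and 2 lower (camera unadjusted p = 0.32), and subtracting each array's median gave 10 and 1 (camera unadjusted p = 0.0188). Proteasome subunits (6 higher and 11 lower of 37 with Brd4 shRNA, 11 and 5 with JQ1), mitochondrial ribosome genes (28 and 12 of 73, 18 and 31) and chaperonin genes (0 and 2 of 7, 0 and 2) did not pass.

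Fos, Egr1 and Arc (Arc was chosen after its value was seen, 1.71 ± 0.34) rose with Brd4 shRNA. A hypothesis was that immediate early genes rise together. The 18 others had a median of 0.36 with 10 higher and 4 lower (camera adjusted p = 0.0387, and adjusted p = 0.311 with an estimated correlation), which is consistent with it, although the bootstrap interval of the median, -0.004 to 0.945, reaches 0. Ier2 stood at 1.63 ± 0.05 and Junb at 1.22 ± 0.12, while Klf4 stood at -1.44 ± 0.07. With JQ1 the same list had 10 higher and 3 lower, a median of 0.27 (camera adjusted p = 0.056).

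The list of ATF4 and unfolded protein response genes rose with JQ1, a call that was lost with an estimated correlation (camera adjusted p = 0.15). That list also holds genes of protein folding, and ATF4 targets alone were not tested. The rise may belong to a wider amino acid response that includes aminoacyl-tRNA synthetases. Their median was 0.10 with JQ1, with 6 higher and 4 lower of 17 (camera adjusted p = 0.372), which leaves this open. The rise of Id1 with JQ1 may be part of a rise of BMP target genes. The 8 others had a median of 0.28 with 4 higher and 2 lower (camera adjusted p = 0.527), and they go both ways, so this stays open as well.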
